A study of Danio rerio with 4 samples.

How the data were processed

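The 4 samples are 10x Genomics 3′ (version 3 chemistry) libraries of dissociated cranial vault cells from zebrafish of 9 mm length, 2 fgfr3+/+ and 2 fgfr3lof/lof, with 1 fish per library. Per the labels' protocols, tissue was dissociated with collagenase and live nucleated cells were sorted (Hoechst positive, viability dye negative) before 6500 cells were loaded per library and sequenced to a mean of 25000 reads per cell. The 6922 and 7262 cells kept in fgfr3+/+ 2 and fgfr3lof/lof 1 exceed the stated 6500, so for these libraries the stated number loaded or the count of cells is off. The genotype and replicate number were taken from the sample titles. The labels name 2 fish per genotype, so fish are the replicates and cells are not.

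The authors deposited raw UMI counts per gene and barcode, made with Cell Ranger on GRCz11 per the submitters' processing notes; the Cell Ranger version is not given in the sources used here. Each matrix lists 6794880 barcodes and 27771 genes, empty droplets included. The authors also deposited 8 tables of pairwise comparisons between fish and 20 tables of cluster markers, with natural log fold changes and p-values, per the file headers; the submitters' processing notes name Seurat 3.0.2 and Seurat 3. No cell annotation was used here, so cell types were rebuilt and may differ from the study's.

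Barcodes of at least 1000 UMIs and 300 genes with at most 10% mitochondrially encoded UMIs were taken as cells. Scrublet's default call marked 0.04, 0, 0 and 0.02% of the barcodes scored (at least 500 UMIs), so it had not worked; instead the cells of highest Scrublet score were removed in each library, 0.8% per 1000 cells (181, 433, 480 and 105 cells). Mixed cells below that rank stay in. Free RNA was read from barcodes of 1 to 100 UMIs. Counts were log-normalised, and 2000 variable genes, 40 principal components and a graph with 6 neighbours from each library went into Leiden clustering at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15), giving 36 clusters. Clusters were named from marker lists fixed before the data were examined: a name needed at least 4 markers and 40% of its markers detected, each at a log2 fold of at least 1 and in at least 10% of cells, with no more markers of another class than of its own among its top 10 genes and without pou2f3 among its top 50. These scoring rules were set after the data were seen. They named 25 clusters in 18 classes and left 11 unnamed, holding 25.01, 24.3, 22.5 and 17.95% of the cells. The osteoblast-like class is cluster 6, osteoprogenitor-like and mesenchymal-like cells are clusters 1 and 4, and fibroblast-like cells are clusters 0, 2, 3 and 17.

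UMI counts were summed per library and class and tested where each library held at least 50 cells. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM factors and filterByExpr, Benjamini-Hochberg adjusted, at a threshold of 0.05; DESeq2 1.42.0 was the other tool. Normalised CPM are UMIs scaled to equal library totals after TMM. Shares were tested with edgeR on cell counts. The 26 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, where at least 5 members were measured; with an estimated correlation 0 of the calls held, and fry gave 0 as well. Cycling shares came from cells thinned to 1000 UMIs.

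Genes were named by a rule fixed before the data were examined: fgfr3 and the other FGF receptors, genes past the threshold, otherwise up to 5 genes of smallest p per direction with an average of at least 4 log2 CPM and no clone name, and up to 4 members of smallest p per list. A few genes that fall under this rule are not reported here. The prefixes LO, CABZ, AL and CT were also treated as clone names, an addition made after the data were seen. The clone-named genes of T cell-like cells and the genes named in unnamed clusters or for differences between classes lie outside this rule and were chosen after their values were seen. The clusters matching OP5 were chosen after the data were seen, and so were the tests of the difference between cell classes, which used the library as a block.

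The edgeR step was tested on simulated counts with 100 genes changed by 2-fold and 100 by 4-fold. It recovered 6 and 87 of them in osteoblast-like cells, 12 and 89 in osteoprogenitor-like and mesenchymal-like cells and 9 and 93 in the clusters matching OP5, with 4, 17 and 11 unchanged genes called; DESeq2 recovered 21 and 91, 25 and 90, and 10 and 89, with 3, 24 and 7 unchanged genes called. The simulations ran on 7852, 10171 and 9588 genes. In the tests within a class, changes of 2-fold were thus mostly missed at this depth and number of fish. The difference test recovered 57 and 99 on 10030 genes and called 10 unchanged ones.

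Alternatives were other normalisations (RLE, upper quartile), no filter on low counts, a replicate block, each library left out in turn, thinned counts, other limits on UMIs and mitochondrial share, no doublet removal, unbalanced neighbours, Leiden resolutions of 0.5 and 2, and clustering without genes that differ. Alternatives of single genes were computed for the genes the text names. A reference gene table of another assembly (GRCz12tu) was used only for gene names and for which genes share a chromosome.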

Results

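Single-cell transcriptomes were collected from the cranial vault of zebrafish of 9 mm length, the stage at which the flat bones of the skull roof are growing. The 4 libraries came from 2 wild-type fish (fgfr3+/+) and 2 fish homozygous for a loss-of-function allele of fgfr3 made with CRISPR/Cas9 (fgfr3lof/lof), 1 fish per library. Fgfr3 is a receptor tyrosine kinase for fibroblast growth factors, and the series asks how it acts on osteoblast expansion and differentiation. The deposited matrices held 56404752 and 66599464 UMIs for fgfr3+/+ 1 and 2, and 62826630 and 33743819 UMIs for fgfr3lof/lof 1 and 2. The study states nearly 28000 cells. The files held 27180 barcodes of at least 400 UMIs and 24184 of at least 1000 UMIs, of which 22286 cells were kept: 4582, 6922, 7262 and 3520 in the order just given. The median cell had 7452.5, 5526.5, 4785 and 5638 UMIs in these libraries. All values for 4 libraries below follow the same order, fgfr3+/+ 1, fgfr3+/+ 2, fgfr3lof/lof 1 and fgfr3lof/lof 2. Fold changes are fgfr3lof/lof minus fgfr3+/+ on the log2 scale. The p-values computed here for single genes and for shares measure the spread between these fish. The camera p-values of gene lists also rest on the preset correlation between genes, so they do not measure that spread alone. Fisher's exact test counts genes, not fish.

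The transcript of the targeted gene was lower in both fgfr3lof/lof libraries than in both fgfr3+/+ libraries in all 7 named classes where it could be tested. In osteoblast-like cells, where it was most abundant, fgfr3 stood at 921, 1035, 297 and 225 normalised CPM (UMIs scaled to equal library totals), a log2 fold change of -1.91 (SE 0.26, n = 2 per genotype). The edgeR adjusted p was 0.165. Chondrocyte-like cells held 326, 489, 37.7 and 118 CPM before normalisation, and fibroblast-like cells 211, 158, 47.2 and 62.0. Levels were low in osteoprogenitor-like and mesenchymal-like cells, at 19.7, 21.5, 8.06 and 11.95 normalised CPM (log2 fold change -1.07, SE 0.31, edgeR adjusted p 1.00). The 3′ tags lie outside the position of the introduced stop codon, and a stop codon allele need not lower its mRNA, so the level neither checks nor refutes a label.

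**Figure D1:**
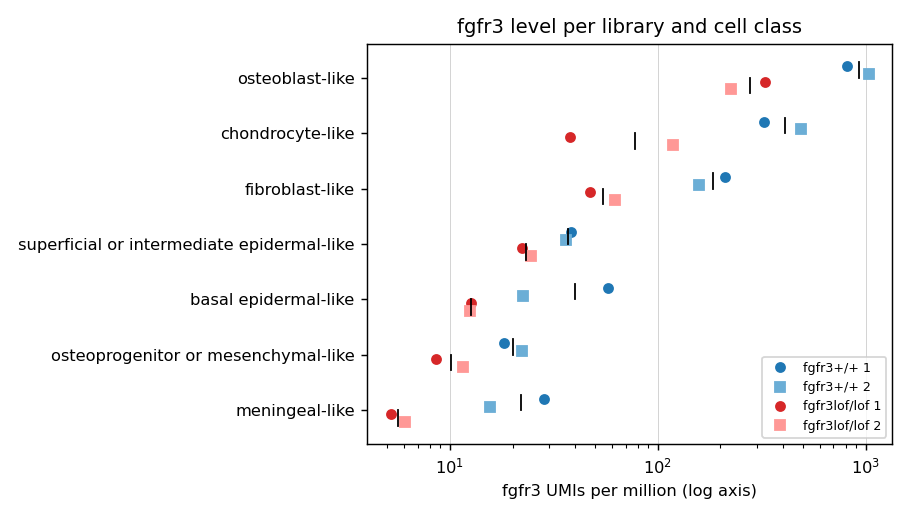
fgfr3 CPM before normalisation (log axis) in each library for the 7 named cell classes where the gene was tested; points are libraries and vertical bars are genotype means. In osteoblast-like cells the fgfr3+/+ libraries lie at 817 and 1033 and the fgfr3lof/lof libraries at 327 and 225 CPM before normalisation.

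Among the other FGF receptors, fgfr4 had a negative log2 fold change in each of the 5 named classes where it was tested. In osteoblast-like cells fgfr4 stood at 123, 122, 86.4 and 49.7 CPM (log2 fold change -0.84), and in osteoprogenitor-like and mesenchymal-like cells at 15.7, 6.83, 4.63 and 4.098 (-1.33). The values of fgfr1a in osteoblast-like cells were 90.5, 79.3, 94.2 and 71.1 CPM (-0.04), those of fgfr1b 13.5, 12.5, 9.56 and 5.14 (-0.79) and those of fgfr2 39.7, 33.25, 38.3 and 55.7 (0.36). In osteoprogenitor-like and mesenchymal-like cells the log2 fold changes were 0.32 for fgfr1a, -0.57 for fgfr1b and 0.21 for fgfr2. Without fgfr3lof/lof 2 the sign turned for fgfr1a in osteoblast-like cells (0.15; 0.054 without fgfr3+/+ 1) and for fgfr2 in osteoprogenitor-like and mesenchymal-like cells (-0.039). None of these passed the threshold.

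Cell composition addresses the expansion of osteoblasts. Osteoblast-like cells made up 7.90, 5.48, 4.90 and 6.68% of the cells kept (log2 fold change -0.21). Osteoprogenitor-like and mesenchymal-like cells made up 14.2, 13.6, 14.2 and 12.4%, and fibroblast-like cells, the most numerous class, 18.3, 20.9, 25.01 and 26.3% (0.39). T cell-like cells held 2.75, 6.65, 4.14 and 4.69%, chondrocyte-like cells 1.11, 1.31, 1.14 and 2.67%, meningeal-like cells 5.63, 4.49, 3.99 and 7.67%, and erythroid-like cells 0.349, 0.448, 0.358 and 1.51%. Basal epidermal-like cells held 6.02, 6.23, 6.38 and 5.09%, and superficial or intermediate epidermal-like cells 9.76, 8.09, 10.1 and 5.45%. In edgeR's quasi-likelihood test 0 of the 29 classes and unnamed clusters passed the threshold, with a smallest adjusted p of 0.981. At an unadjusted p under 0.05 there was 1, unnamed cluster 31, led by chemokine genes such as ccl38.6, at 1.83, 0.578, 0.358 and 0.199%. No other tool was run on the shares, and with 2 libraries against 2 the exact permutation test cannot go below a two-sided p of 0.333. Collagenase digestion and the sort for live nucleated cells can set these shares. Unnamed clusters 5, 12 and 22, with markers of named classes, were also kept out by rules set after the data were seen. Cluster 5, led by col14a1a and igsf10, was at 6.22, 6.62, 5.95 and 6.79%. Cluster 22, with pou2f3 among its leading genes, was at 1.79, 0.896, 1.29 and 0.568%. Cluster 12, with 6 of 10 T cell markers, was at 5.19, 4.25, 3.36 and 3.15%, so the T cell-like share depends on that rule.

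**Figure D2:**
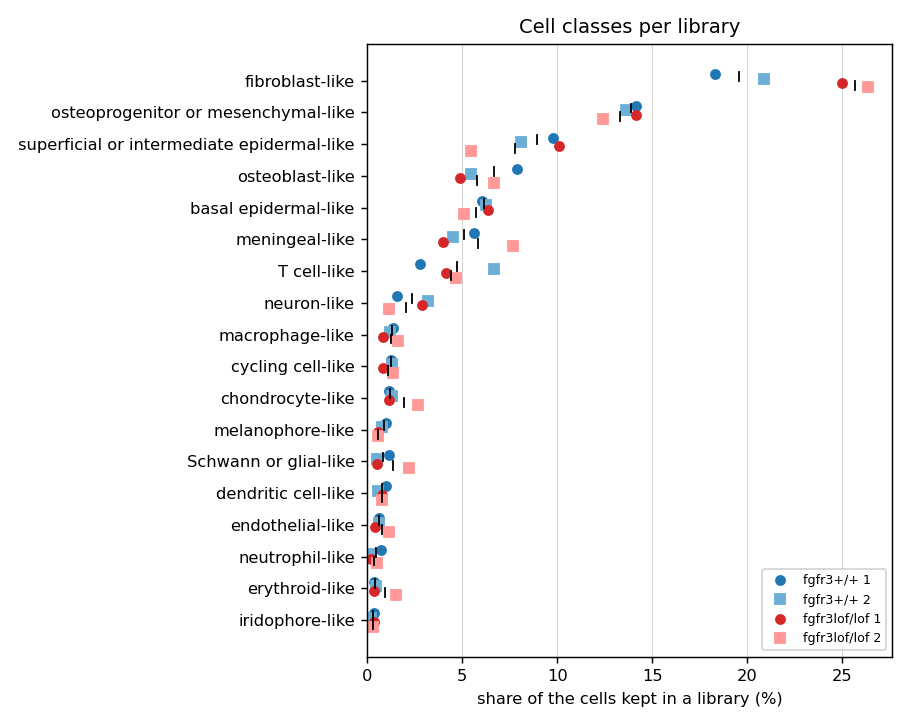
Share of the cells kept (%) for each named class in each library; points are libraries and vertical bars are genotype means. Osteoblast-like cells lie between 4.90 and 7.90% and fibroblast-like cells between 18.3 and 26.3%.

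Within the osteoblast lineage, which here held clusters 1, 4 and 6, the osteoblast-like cluster 6 (col10a1a, bglap, ifitm5 and spp1 lead it) took 35.8, 28.6, 25.7 and 35.0% of the cells. Cluster 1, led by fgl1 and rspo4, took 31.5, 41.6, 40.0 and 25.6%. Cluster 4, led by vcanb, has2 and fgfbp2a, took 32.7, 29.7, 34.3 and 39.4%. Clusters 1 and 4 each had 6 of 14 osteoprogenitor or mesenchymal markers, while unnamed cluster 5, with 8 of 14, was left out of the lineage. Clusters 2 and 3, which matched the group OP5 of the authors' deposited tables, were left out too and count as fibroblast-like in the shares above. The shares within the lineage therefore do not cover these cells. With edgeR 0 of 3 clusters passed and 0 had an unadjusted p under 0.05; all adjusted p were 0.751, and no other tool was run. Some defining genes of these clusters, bglap among them, themselves had different values in the genotypes, so the cells were also clustered with 233 of the 2000 variable genes left out, a setting added after the data were seen. Osteoblast-like cells then made up 7.86, 5.48, 4.92 and 6.70%, and 0 of 18 classes passed (edgeR, smallest adjusted p 0.881). Some classes held partly other cells in this setting. Cells shared with the first clustering made up a fraction of 0.993 of the cells in either for osteoblast-like cells, but 0.529 for osteoprogenitor-like and mesenchymal-like, 0.459 for T cell-like and 0.342 for fibroblast-like cells. Fibroblast-like cells then took 7.35, 6.79, 8.21 and 10.2% and T cell-like cells 10.1, 12.2, 8.95 and 9.57%.

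The share of cycling cells bears on expansion as well. After thinning to 1000 UMIs per cell, cells with at least 3 UMIs of the cell cycle list made up 1.48, 6.20, 4.91 and 7.59% of the osteoblast-like, osteoprogenitor-like and mesenchymal-like cells. The means were 3.84 ± 3.33% in fgfr3+/+ and 6.25 ± 1.89% in fgfr3lof/lof (SD, n = 2 per genotype; exact permutation p 0.667). Without thinning the means were 49.5 and 40.4%, in the opposite order, but a cut of 3 UMIs then depends on the UMIs per cell. These had medians of 9357, 7428, 5518 and 7260, so the unthinned values do not compare cycling between the libraries. Without fgfr3+/+ 1 the difference of 2.41 percentage points shrank to 0.0533. Cells of a separate class of cycling cells, cluster 23, are not in these shares. With its cells placed in the cluster of most similar profile, the means were 4.13 ± 3.33% and 6.56 ± 2.04% (SD, n = 2 per genotype). By the same thinned cut, T cell-like cells held 0.794, 3.04, 1.33 and 2.42% and meningeal-like cells 1.16, 3.54, 1.72 and 4.07%. The share was thus lowest in fgfr3+/+ 1 outside the lineage too.

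In osteoblast-like cells (362, 379, 356 and 235 cells) the genes of smallest p with higher values in fgfr3lof/lof included phospho1, the phosphatase that supplies phosphate for mineralisation and a marker of the class, at 101, 103, 175 and 298 CPM (log2 fold change 1.21). Others were igfbp1a, an insulin-like growth factor binding protein, at 19.9, 52.8, 128 and 182 CPM (2.09, SE 0.46), dpt, the matrix protein dermatopontin and a fibroblast marker, at 40.7, 61.7, 125 and 218 (1.74, SE 0.37), selenok, a selenoprotein of the endoplasmic reticulum, at 13.7, 9.40, 35.6 and 53.5 (1.93, SE 0.35), and sh3d21 at 12.6, 7.95, 25.7 and 32.6 (1.49). Lower values were seen, besides fgfr3, for tnmd, the tendon and ligament gene tenomodulin, at 700, 686, 241 and 274 CPM (-1.43, SE 0.25). The alcohol dehydrogenase gene adh8a stood at 73.1, 69.4, 14.9 and 10.3 (-2.48, SE 0.32) and c1qtnf5 at 34.3, 28.7, 7.77 and 2.57 (-2.53, SE 0.46). The osteocalcin gene bglap, which helps define the class, was at 35323, 10831, 5247 and 8531 CPM (-1.74, SE 0.56). Its log2 fold change was -0.66 without fgfr3+/+ 1 and -2.36 without fgfr3+/+ 2. By edgeR 0 of 8219 genes passed the adjusted threshold of 0.05 (smallest adjusted p 0.0719). At an unadjusted p under 0.05, 116 had higher and 184 lower values. Together these were a smaller fraction of the genes tested than the 0.05 that no effect would give, so their number is no sign of an effect. DESeq2 called 16, of which 6 were higher and 10 lower, fgfr3, tnmd, igfbp1a and dpt among them. Without fgfr3+/+ 2 edgeR called 7 genes.

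**Figure D3:**
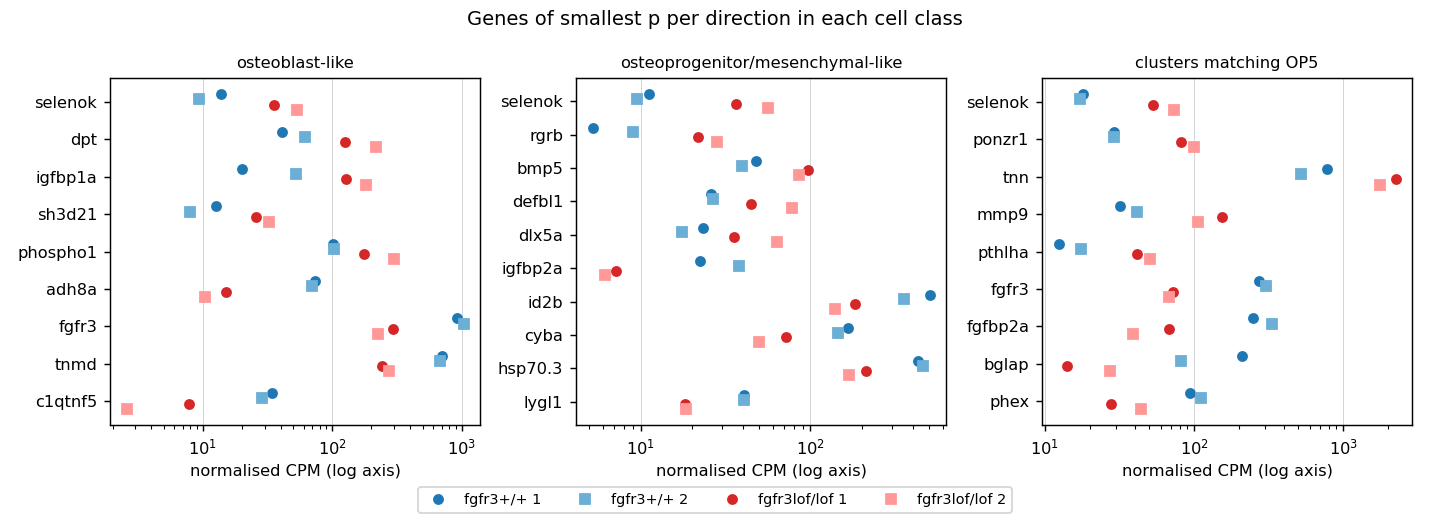
Normalised CPM (log axis) per library of up to 5 genes of smallest p in each direction in 3 groups of cells; each point is a library. In osteoblast-like cells tnmd lies at 700 and 686 in fgfr3+/+ and at 241 and 274 CPM in fgfr3lof/lof.

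The lists of bone and signalling genes were tested in osteoblast-like cells with camera. Of 28 measured genes of osteoblast differentiation and bone matrix 10 had higher and 18 lower values (median log2 fold change -0.12, adjusted p 0.622). The gene sost, an inhibitor of Wnt signalling made by osteocytes, was at 69.0, 61.7, 36.2 and 21.4 CPM. Suture mesenchyme and osteoprogenitor genes split 10 to 10 (adjusted p 0.946), with pdgfra at 12.9, 12.8, 19.7 and 33.8 CPM and zic1 at 5.36, 3.37, 0.598 and 2.14. Among 8 FGF receptors and ligands (adjusted p 0.365) 1 was higher and 1 lower when adjusted over the list alone, fgf10a (1.501, 0.482, 4.78 and 5.57 CPM) and fgfr3, against 0 over all genes. The 17 FGF and ERK pathway targets had a median of -0.06, a mean of 0.07 and a test pointing up (adjusted p 0.855), with etv5b at 13.1, 18.6, 30.2 and 21.0 CPM and etv4 at a log2 fold change of 0.70 (-0.39 without fgfr3lof/lof 1). Canonical Wnt genes (13 higher, 14 lower, adjusted p 0.994; wnt10a 1.29, 1.93, 7.17 and 5.57 CPM, dkk1b 13.5, 17.8, 34.4 and 29.99), BMP genes (14 and 9, 0.946; bmp6 14.1, 17.1, 30.8 and 21.4, nog2 log2 -1.21), Hedgehog genes (8 and 2, 0.123), Notch genes (4 and 6, 0.573; heyl 54.0, 48.0, 27.2 and 27.4) and retinoic acid genes (4 and 7, 0.946) did not pass. For TGF-beta genes the median was 0.26, the mean -0.15 and the test down (adjusted p 0.305). In the IGF axis (4 and 6, adjusted p 0.855) igfbp1a passed adjusted over the list alone, while igfbp2a was at 52.1, 23.9, 14.3 and 17.6 CPM. Among retinoic acid genes crabp1a passed adjusted over the list alone (6.43, 2.17, 14.3 and 34.7 CPM), and crabp2b had a log2 fold change of -1.33.

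Cell cycle genes were the list with the smallest camera p in osteoblast-like cells: 14 of 16 had higher values (median log2 fold change 0.85, adjusted p 6.34e-09, but adjusted p = 0.849 with an estimated correlation). The DNA replication genes dut and mcm6 stood at 1.501, 4.096, 9.27 and 9.00 CPM and at 6.002, 3.86, 9.56 and 9.85. Fibrillar collagen and extracellular matrix genes had lower values in 27 of 32 members (median -0.56, adjusted p 2.51e-07, adjusted p = 0.849 with an estimated correlation), with lum, the proteoglycan lumican, at 116, 72.8, 43.6 and 42.0 CPM and col16a1 at 14.4, 15.2, 6.28 and 5.997. A separate set of 106 genes, each at least 10 times higher in clusters 2 and 3 than in osteoblast-like cells, summed to 2590.7, 2882.9, 2417.3 and 1616.8 CPM in osteoblast-like cells. Dissociation and immediate early stress genes were lower in 29 of 34 (adjusted p 0.00258, adjusted p = 0.987 with an estimated correlation), with atf3 at 107, 104, 65.5 and 46.7 CPM and hsp90aa1.2 at 417, 268, 129 and 208. Inflammation genes were lower in 10 of 11 (adjusted p 0.0153, adjusted p = 0.849 with an estimated correlation), with csf1a at a log2 fold change of -2.21 and the chemokine gene cxcl12a at 35.8, 34.7, 20.6 and 4.71 CPM. Cytosolic ribosomal protein genes were lower in 82 of 86 (median -0.17, adjusted p 0.00976, adjusted p = 0.987 with an estimated correlation), for example rpl38 at 3210, 2931, 1984 and 2344 CPM. Erythroid transcripts, which belong to red blood cells, were higher in all 6 members (adjusted p 2.29e-06, adjusted p = 0.849 with an estimated correlation); hbae5 stood at 0, 3.61, 40.1 and 7.71 CPM.

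The other lists did not pass in osteoblast-like cells. Endoplasmic reticulum and unfolded protein response genes were lower in 25 of 38 (adjusted p 0.285; herpud1 15.4, 16.1, 9.27 and 6.85 CPM, pdia6 log2 -0.80), hypoxia and glycolysis genes higher in 8 of 12 with a median of 0.07 and a mean of -0.03 (0.994; ldha -0.68), osteoclast genes lower in 7 of 7 (0.209; ctsk 96.0, 130, 87.6 and 76.7 CPM) and mitochondrially encoded genes higher in 10 of 13 (0.855; mt-cyb 1560, 1609, 1493 and 2640, log2 0.38 and -0.085 without fgfr3lof/lof 2). Chondrocyte genes split 4 to 4, with a median of 0.04, a mean of -0.10 and a test pointing down (adjusted p 0.855). The cartilage collagen gene col9a2 was lower adjusted over the list alone (7.93, 8.92, 3.29 and 1.71 CPM). Epidermal transcripts had a median of 0.10, a mean of -0.05 and a test pointing down (adjusted p 0.994), with icn at 5610, 4785, 3244 and 3422 CPM and krtt1c19e at 13.9, 5.54, 35.3 and 16.7. Immune, neural and muscle transcripts had 3, 1 and 1 measured members, under the minimum of 5, and were not tested. No list held a member past the threshold over all genes.

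In osteoprogenitor-like and mesenchymal-like cells (649, 944, 1028 and 437 cells) the genes of smallest p with higher values were selenok at 11.3, 9.54, 36.4 and 56.4 CPM (log2 fold change 2.15, SE 0.32), rgrb at 5.23, 8.97, 21.8 and 28.0, bmp5, a bone morphogenetic protein ligand, at 47.6, 39.4, 97.1 and 85.0 (1.07, SE 0.26), defbl1 at 25.9, 26.6, 45.0 and 78.2, and dlx5a, a homeobox transcription factor and an osteoblast marker, at 23.3, 17.5, 35.5 and 63.9 (1.28). Lower values were seen for igfbp2a at 22.3, 37.7, 7.21 and 6.15 CPM (-2.16, SE 0.36), id2b, a target of BMP signalling, at 502, 356, 182 and 139 (-1.42, SE 0.30), the NADPH oxidase subunit gene cyba at 166, 145, 72.1 and 49.9 (-1.35), the heat shock gene hsp70.3 at 431, 457, 213 and 169 (-1.22) and the lysozyme gene lygl1, a macrophage marker, at 40.8, 40.4, 18.4 and 18.4 (-1.14). By edgeR 0 of 10534 genes passed (smallest adjusted p 0.106). At an unadjusted p under 0.05, 149 had higher and 191 lower values, again a smaller fraction than the 0.05 that no effect would give. DESeq2 called 10, 4 higher and 6 lower. On simulated counts of these cells DESeq2 called 24 unchanged genes, beside 25 and 90 recovered of 100 each changed by 2-fold and 4-fold. With that many planted changes, the simulation does not give how many of the 10 are false. Leaving out a library gave 10, 32, 77 and 6 genes, in the order of the libraries.

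Stress genes had lower values in these cells in 29 of 34 members (median log2 fold change -0.66, camera adjusted p 1.65e-16, adjusted p = 0.821 with an estimated correlation). Adjusted over the list alone 6 fell, against 0 over all genes; fosb stood at 1586, 1296, 700 and 456 CPM and hsp70.2 at 397, 328, 171 and 123. Cell cycle genes had higher values in 20 of 21 (median 0.76, adjusted p 1.94e-12, adjusted p = 0.821 with an estimated correlation), with the proliferation marker mki67 at 1.81, 2.28, 6.35 and 6.83 CPM and tyms at 3.42, 4.13, 8.06 and 9.22. This list turned to the other direction in cells of at least 2000 UMIs (adjusted p 0.997) and with a mitochondrial share of up to 20% (0.849). Chondrocyte genes were higher in 9 of 14 (0.31, adjusted p 0.00356, adjusted p = 0.821 with an estimated correlation); matn4, a cartilage matrix gene, passed adjusted over the list alone (3.82, 4.13, 9.44 and 17.1 CPM) and col2a1a had a log2 fold change of 1.08. Erythroid transcripts were higher in 5 of 5 (adjusted p 4.13e-04, adjusted p = 0.821 with an estimated correlation), with hbae5 at 0, 3.70, 3.09 and 11.6 CPM, and mitochondrially encoded genes in 10 of 13 (0.0378, adjusted p = 0.955 with an estimated correlation), with log2 fold changes of 0.79 for mt-nd2 and 0.43 for mt-cyb. The mitochondrially encoded list also turned without fgfr3lof/lof 2 (adjusted p 0.671).

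The remaining lists did not pass in these cells. Bone matrix genes split 9 to 10 (adjusted p 0.781; bglap 45.4, 23.3, 4.46 and 14.002 CPM), suture genes 10 to 11 (0.816; fap -0.41, 0.017 when clustered without genes that differ), FGF and ERK targets 9 to 9 (0.837; fosl1a 242, 205, 174 and 102) and BMP genes 12 to 12 (0.803), where id2b fell adjusted over the list alone. FGF receptors and ligands had a median of 0.06, a mean of -0.04 and a test pointing down (0.803), with fgf18a at 6.03, 3.27, 9.95 and 7.51 CPM. Wnt genes had a median and a mean of 0.02 and a test pointing down (0.803), with rspo1 at 43.0, 30.3, 15.96 and 20.5 and notum1a at 19.5, 24.8, 14.1 and 10.2. Notch genes had a median of 0.15, a mean of -0.02 and a test pointing down (0.803; heyl 175, 146, 97.3 and 99.7). Retinoic acid genes had a median of -0.03, a mean of 0.14 and a test pointing up (0.567). The gene aldh1a2, a retinoic acid synthesis enzyme, rose adjusted over the list alone (4.02, 7.40, 24.9 and 16.4 CPM), and aldh1a3 had a log2 fold change of 1.25. Inflammation genes had a median of -0.07, a mean of 0.08 and a test pointing up (0.758). The acute phase gene saa rose adjusted over the list alone (2.61, 6.98, 24.5 and 27.0 CPM). The log2 fold change of saa turned from 2.38 to -0.064 with a mitochondrial share of up to 20%. The IGF axis was lower in 9 of 12 (0.104), with igfbp2a lower adjusted over the list alone, TGF-beta genes in 7 of 11 (0.552), hypoxia genes in 12 of 15 (0.0702; eno1a -0.47) and ribosomal protein genes in 72 of 88 (0.104). Hedgehog genes (0.803), osteoclast genes (0.803), matrix genes (18 and 19, 0.529), endoplasmic reticulum genes (19 and 18, 0.980; xbp1 467, 494, 284 and 288) and epidermal transcripts (8 and 4, 0.340; krtt1c19e 15.9, 12.8, 51.0 and 21.9) did not pass either. Immune, neural and muscle transcripts, with 3, 3 and 1 members, were not tested.

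The authors' deposited tables compare genotypes in osteoblasts (OB) and in a group named OP5. By the correlation of those fold changes with the ones recomputed here, OB matched cluster 6 and OP5 matched clusters 2 and 3, which the markers name fibroblast-like and which tnn, en1b, nog2 and nog3 lead. These clusters were therefore tested as a further unit, chosen after the data were seen (677, 686, 934 and 741 cells). There fgfr3 was at 270, 302, 71.8 and 68.0 CPM (log2 fold change -2.03, SE 0.27, edgeR adjusted p 0.3298), and fgfbp2a, an FGF binding protein, at 250, 332, 67.7 and 38.9 (-2.45, SE 0.36). The other genes of smallest p with lower values included bglap (211, 81.4, 14.008 and 27.4 CPM, -2.82) and phex, a peptidase of phosphate handling in bone (93.8, 111, 27.6 and 43.9, -1.52). Higher values were seen for tnn, a tenascin of the extracellular matrix, at 777, 519, 2242 and 1764 CPM (1.63, SE 0.28), the matrix protease gene mmp9 at 31.9, 41.6, 153 and 106 (1.82, SE 0.31), pthlha, a parathyroid hormone-like ligand, at 12.4, 17.3, 41.2 and 50.4, ponzr1 at 29.1, 29.2, 81.2 and 99.7, and selenok at 18.01, 17.1, 53.0 and 72.8. The other receptors had log2 fold changes of 0.56 for fgfr1a (64.0, 59.7, 101 and 81.4 CPM), -0.37 for fgfr1b (0.20 without fgfr3lof/lof 2), -0.12 for fgfr2 (0.052 without it) and -1.60 for fgfr4 (40.4, 29.2, 17.02 and 5.73). By edgeR 0 of 9912 genes passed (smallest adjusted p 0.0517). At an unadjusted p under 0.05, 153 had higher and 241 lower values, a smaller fraction than the 0.05 that no effect would give. DESeq2 called 20, 7 higher and 13 lower. Basal epidermal-like, superficial or intermediate epidermal-like, T cell-like and macrophage-like cells and unnamed clusters 12 and 15, which are not bone, also held bglap, at a mean of 80.75, 17.28, 7.04 and 6.69 CPM before normalisation. Without the basal epidermal-like cells, which alone stood at 270.59 CPM in fgfr3+/+ 1, that mean was 42.78, 17.996, 7.795 and 7.33. Leaving out 1 library at a time gave 0 to 4 genes.

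In the clusters matching OP5, FGF and ERK targets had lower values in 14 of 18 members (median log2 fold change -0.19, camera adjusted p 0.00566, adjusted p = 0.738 with an estimated correlation); fgfbp2a, which is also in the chondrocyte list, fell adjusted over the list alone, and dusp6, an ERK phosphatase, stood at 59.7, 51.2, 45.3 and 30.5 CPM. BMP genes were lower in 17 of 26 (-0.26, adjusted p 0.00268, adjusted p = 0.738 with an estimated correlation), with id2b at 382, 300, 154 and 68.5 CPM and id2a at 289, 247, 158 and 116, and bone matrix genes in 14 of 25 (-0.20, adjusted p 0.0128, adjusted p = 0.738 with an estimated correlation), where bglap and phex fell adjusted over the list alone. Stress genes were lower in 25 of 34 (adjusted p 5.27e-05, adjusted p = 0.738 with an estimated correlation; hsp70.1 147, 136, 51.9 and 69.4 CPM, hsp90aa1.2 342, 196, 123 and 107), ribosomal protein genes in 82 of 87 (-0.31, adjusted p 4.67e-09, adjusted p = 0.738 with an estimated correlation; rpl38 3170, 2658, 1786 and 1877), and erythroid transcripts were higher in 5 of 5 (adjusted p 0.00566, adjusted p = 0.738 with an estimated correlation; hbbe2 log2 1.70, -0.15 without fgfr3lof/lof 2). Without fgfr3lof/lof 2 the FGF and ERK targets (adjusted p 0.961) and the stress genes (0.979) turned to the other direction, as did the erythroid transcripts without fgfr3+/+ 1 (0.834).

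Among the lists that did not pass in the clusters matching OP5, FGF receptors and ligands (adjusted p 0.326) held 1 member that rose adjusted over the list alone, fgf18a (18.4, 11.11, 39.7 and 42.0 CPM), and 2 that fell, fgfr3 and fgfr4, against 0 over all genes. Its relative fgf18b, which did not pass, was at 21.5, 13.7, 31.2 and 30.1. Wnt genes split 19 to 14 (0.669), with the Wnt antagonist genes frzb at 78.1, 56.1, 148 and 152 CPM and dkk1a at 8.03, 5.17, 14.9 and 17.9. Matrix genes were higher in 27 of 38 (0.0966), with tnn past the threshold adjusted over the list alone and col5a3a at a log2 fold change of -0.96. Inflammation genes split 8 to 7 (0.183). The genes mmp9 and csf1b (33.9, 30.8, 66.8 and 64.9 CPM) rose adjusted over the list alone, as did mmp9 in the osteoclast list (4 and 3, 0.373). The IGF axis was lower in 10 of 12 (0.0594; igf2b 210, 175, 136 and 66.8), Notch genes in 8 of 12 (0.200; hey1 log2 -1.11) and hypoxia genes in 10 of 13 (0.373). TGF-beta genes had a median of 0.10, a mean of 0.00 and a test pointing down (0.773), and immune transcripts a median of -0.21, a mean of 0.06 and a test pointing up (0.326). Chondrocyte genes were higher in 11 of 16 (0.567; sox6 log2 0.69, col9a2 289, 129, 88.8 and 68.2 CPM) and cell cycle genes in 13 of 18 (0.251). Endoplasmic reticulum genes were higher in 26 of 37 (0.130; calr log2 0.62), epidermal transcripts in 10 of 12 (0.0966; krtt1c19e 1.26) and mitochondrially encoded genes in 12 of 13 (0.0517; mt-cyb 0.62). Suture genes (0.567; fap -0.67), Hedgehog genes (0.632) and retinoic acid genes (0.840; rbp4 -0.53) did not pass, and neural and muscle transcripts, with under 5 members, were not tested.

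The authors' deposited tables list each fgfr3+/+ fish against each fgfr3lof/lof fish as natural log fold changes. Of the 491 genes listed in any OB comparison 18 had the same sign in all 4. Of these 9 were lower in fgfr3lof/lof (fgfr3, tnmd, bglap and ism1 among them) and 9 higher (igfbp1a, phospho1, itm2ba and furina among them). In the authors' deposited tables fgfr3 had fgfr3+/+ minus fgfr3lof/lof values of 0.7335, 1.0354, 0.9684 and 1.2703 in OB, and bglap of 1.6972, 1.294, 0.8068 and 0.4036. Of the 642 genes listed for OP5 38 had the same sign in all 4. Of these 21 were lower (fgfbp2a, fgfr3, bglap, id2b and phex among them) and 17 higher (aqp3a, col12a1b, frzb, ponzr1 and selenok among them). The authors' deposited tables give fgfbp2a 0.8226, 0.9766, 1.0939 and 1.2479 and aqp3a -1.1673, -0.8095, -0.9521 and -0.5943 in OP5. The 4 comparisons share libraries, so such overlaps can arise without any effect. In osteoblast-like cells, simulated libraries with no effect gave a mean of 28.6 genes (15 to 44 in 100 sets). The same rule on the observed summed counts gave 15. In the clusters matching OP5 the simulated mean was 30.5 (20 to 46), against 32 observed. The observed 15 equals the lowest simulated set, so the simulated libraries may vary more than the real ones. They were also summed counts, not single cells, so they cannot tell how many of the 18 and 38 genes arose without an effect. Applied to the cells here, the rule gave 18 and 38 genes for the genotype, 32 and 48 when the libraries were split by replicate number, and 10 and 7 for the crossed split.

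In the other cell classes 4 genes passed by edgeR, all with higher values in fgfr3lof/lof. The clone-named pair among them lies outside the naming rule and was chosen after its values were seen. A split pairing fgfr3+/+ 2 with fgfr3lof/lof 1, which ignores genotype, called 6 genes in basal epidermal-like, 2 in macrophage-like and 1 in T cell-like cells by edgeR. Passing the threshold in these classes therefore does not by itself mark an effect of the genotype. In T cell-like cells hbegfb, an epidermal growth factor-like ligand, was at 11.2, 1.35, 92.2 and 146 CPM (log2 fold change 4.86, SE 0.61, edgeR adjusted p 0.00992). There si:ch1073-209h18.1 was at 0, 0, 57.2 and 34.7 CPM and BX322792.1 at 0, 0, 39.1 and 32.9, each with an edgeR adjusted p of 0.00755. Set against a floor of 3 counts over the fgfr3+/+ group, they were at least 34.5-fold and 25.9-fold higher in pooled counts. In basal epidermal-like cells mhc1zfa, an MHC class I gene of a family whose gene content varies between haplotypes, was at 0.685, 0.875, 34.02 and 39.0 CPM (5.49, SE 0.40, edgeR adjusted p 0.0207). Of 3615 genes in T cell-like cells 120 had an unadjusted p under 0.05, and of 9857 in basal epidermal-like cells 214. DESeq2 called 3 and 13. In these and the 5 classes that follow, such genes were a smaller fraction than the 0.05 that no effect would give. By edgeR 0 genes passed in fibroblast-like cells (246 at an unadjusted p under 0.05; DESeq2 called 12), meningeal-like cells (285; 6), superficial or intermediate epidermal-like cells (214; 16), chondrocyte-like cells (83; 0) and macrophage-like cells (104; 1). Over these 7 classes the count was 73, 98, 177 and 238 without each library in turn. With no doublets removed it was 1 over 6 classes, since chondrocyte-like cells then fell under 50 cells per library (19, 47, 25 and 46). Reads of mhc1zfa may be shared with near-identical family members, so its level is uncertain.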

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

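The tests of the difference between cell classes, and the gene tests in cluster 15 and in the clusters matching OP5, were chosen only after the results were seen, as were the genes named for them and the values without a library or class. The genotype effect differed between osteoblast-like cells and the clusters matching OP5 for 38 of 10385 genes (edgeR interaction test with the library as a block). Of these 10 were positive and 28 negative, and 713 genes had an unadjusted p under 0.05. In its simulation 10 unchanged genes were called, beside 57 and 99 recovered of 100 each changed by 2-fold and 4-fold. With that many planted changes, it does not give how many of the 38 are false. Between osteoblast-like and osteoprogenitor-like or mesenchymal-like cells the effect differed for 0 of 10821 genes (edgeR, 502 at an unadjusted p under 0.05). DESeq2 was not run on this test. Leaving out a library moved the 38 to between 19 (without fgfr3+/+ 1, 12 of them shared) and 136 (without fgfr3+/+ 2, 32 shared), with 64 and 44 without fgfr3lof/lof 1 and 2.

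The bone gene phex was at 812, 867, 732 and 1275 CPM in osteoblast-like cells and at 79.9, 94.1, 23.4 and 37.3 in the clusters matching OP5, a difference of log2 fold changes of 1.76 (edgeR adjusted p 5.68e-04). For fgfbp2a the values were 1524, 2293, 2067 and 2097 against 213, 283, 57.4 and 33.0 CPM (difference 2.64, edgeR adjusted p 0.00317). The tendon gene tnmd went the other way, at 816, 810, 287 and 316 against 693, 537, 535 and 514 (-1.22, edgeR adjusted p 0.0062). The same sign was seen for lum (135, 85.8, 52.0 and 48.4 against 3308, 2178, 3004 and 2580; -1.15), for the homeobox gene en1b (140, 102, 73.7 and 69.7 against 345, 279, 529 and 463; -1.41) and for lgals2a (275, 349, 159 and 120 against 226, 381, 397 and 296; -1.38). The water channel gene aqp3a stood at 79.4, 57.4, 85.8 and 35.6 against 178, 108, 496 and 224 CPM (-1.54, edgeR adjusted p 0.00418). Osteocalcin, bglap, was at 41147, 12774, 6250 and 9839 against 180, 69.3, 11.9 and 23.3 (difference 1.18, edgeR adjusted p 0.00179).

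Free RNA was weighed as a source of the lower bglap and of the lower values of genes far higher in the clusters matching OP5. In 6 groups of cells that are not bone (basal and superficial or intermediate epidermal-like, T cell-like and macrophage-like cells, clusters 12 and 15) the log2 ratio of bglap between genotypes ranged from -5.396 to -1.40; the lowest is that of basal epidermal-like cells, at 270.59 CPM in fgfr3+/+ 1 against 13.72 in fgfr3+/+ 2, and was -2.023 without fgfr3+/+ 1. Its median, -2.055, lay just inside the bound of 0.5 set around the -2.552 of barcodes of 1 to 100 UMIs, consistent with osteocalcin RNA shed by osteoblasts; meningeal-like (-2.948) and chondrocyte-like cells (-3.021) were not among the 6. Without fgfr3+/+ 1 the median was -1.28 against -1.563 in free RNA, and without fgfr3+/+ 2 it was -2.585 against -3.133, a distance of 0.548 that misses the bound; without fgfr3lof/lof 1 and 2 the distance was 0.244 and 0.338. In the clusters matching OP5 bglap lay 2.053 to 4.713 times above the mean of those 6, so part of it may be free RNA; the level left after subtraction still had a log2 ratio of -2.586 (1.854 to 4.526 times and -2.934 without basal epidermal-like cells), and the sources cannot be told apart there because the lowest ratio lies between the bounds set. For the 106 genes far higher in the clusters matching OP5, which were lower in osteoblast-like cells in 94 cases, free RNA is argued against: their log2 ratio had a median of 0.069 over 4 other classes and 0.383 in free RNA, against -0.44 in osteoblast-like cells. The last was -0.179 without fgfr3lof/lof 2, -0.759 without fgfr3lof/lof 1, -0.515 without fgfr3+/+ 1 and -0.361 without fgfr3+/+ 2. The median stayed between -0.043 and 0.326, but macrophage-like cells, at -0.647, lay below osteoblast-like cells without fgfr3+/+ 1. Mixed cells, doublets and an effect of the genotype on osteoblasts stay open and were not tested.

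Unnamed cluster 15, whose genes were tested in no comparison of the report, is led by il4 and a group of si:dkey-21e2 genes. There 5 of 2181 genes passed by edgeR: glrx (18.3, 6.40, 132 and 147 CPM), si:dkey-78l4.2 (1373, 748, 3585 and 3729.9) and si:dkey-21e2.13 (5911, 4259.5, 10433 and 13485), itself a leading gene of the cluster, rose, and jdp2b (1222, 1231, 365.0 and 277) and zgc:158343 (98.6, 86.3, 16.1 and 14.4) fell.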

How the results depend on the processing

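Alternatives in the clusters matching OP5, the tests of differences between classes and the clustering without genes that differ were chosen only after the data were seen. Without a library 1 fish is left in a genotype and is assumed to vary like the other genotype; edgeR's tests within a class recovered 6 to 12 of 100 simulated 2-fold changes at this depth, and its difference test 57. The number of genes called in osteoblast-like cells (0 by edgeR) was 16 with DESeq2, 62 with no filter on low counts and 0 to 7 with a library left out. In osteoprogenitor-like and mesenchymal-like cells (0) it was 10, 84 and 6 to 77, in all other classes (4) 51, 344 and 73 to 238, and in the clusters matching OP5 (0) 20, 95 and 0 to 4. Other classes gave 8 genes with thinned counts and 1 with no doublets removed, the latter over 6 classes without chondrocyte-like cells. The clusters matching OP5 gave 2 with upper quartile factors, 2 with no doublets removed and 2 when clustered without genes that differ. The cause was not tested in any of these.

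The replicate numbers are not said to mark a shared day, and deviations of same-numbered libraries correlated at 0.1292 in osteoblast-like cells, 0.0736 in osteoprogenitor-like and mesenchymal-like cells and 0.1294 in the clusters matching OP5. In the other classes the correlation ranged from -0.0838 in macrophage-like to 0.333 in superficial or intermediate epidermal-like cells, with -0.0693 in fibroblast-like, -0.0445 in basal epidermal-like, 0.0825 in T cell-like, 0.116 in meningeal-like and 0.211 in chondrocyte-like cells. With the replicate block 11 genes were called in the other classes and 4 in the clusters matching OP5, where fgfr3 (log2 fold change -2.03) passed and 11 lists did; osteoblast-like and osteoprogenitor-like cells stayed at 0. Splitting the libraries by replicate number gave 754 genes at an unadjusted p under 0.05 in osteoblast-like cells, against 300 for the genotype, 856 against 340 in osteoprogenitor-like and mesenchymal-like cells and 890 against 394 in the clusters matching OP5; 8, 0 and 1 passed the adjusted threshold. In each of the other 7 classes it also gave more than the genotype (198 to 2127). The crossed split paired fgfr3+/+ 2 with fgfr3lof/lof 1. It gave 245 genes in osteoblast-like cells, 513 in osteoprogenitor-like and mesenchymal-like cells and 339 in the clusters matching OP5. In the other classes it gave more than the genotype (for example 881 against 246 in fibroblast-like cells), except in superficial or intermediate epidermal-like cells (179 against 214). At the adjusted threshold the crossed split called 1 gene in each of the first 3 groups, against 0 for the genotype. It called 6 in basal epidermal-like, 2 in macrophage-like and 1 in T cell-like cells, against 1, 0 and 3 for the genotype. These counts therefore cannot tell whether the replicate numbers mark a shared structure.

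The main fit called 6 lists in osteoblast-like cells, 5 in osteoprogenitor-like and mesenchymal-like cells and 6 in the clusters matching OP5. Of these 0 passed with an estimated correlation and 0 with fry. The cell cycle list in osteoprogenitor-like cells turned direction with at least 2000 UMIs (adjusted p 0.997) and a mitochondrial share of up to 20% (0.849). With a library left out the mitochondrially encoded list there ranged from 2.06e-05 to 0.671. In the clusters matching OP5 the adjusted p of FGF and ERK targets then ranged from 1.45e-06 to 0.961, of stress genes from 1.63e-12 to 0.979 and of erythroid transcripts from 3.66e-24 to 0.834, each with the direction turned at the upper end. For the lists called in the main fit, 115 values kept direction and side of the threshold without a library left out, 36 were weaker and 2 turned. With a library left out 4 turned. Lists that the main fit did not call are not in these counts.

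Of the named genes 1799 values kept direction and side of the threshold with all libraries, 66 newly passed, 5 no longer passed and 4 turned; with a library left out these were 476, 15, 4 and 8. In osteoblast-like cells fgfr1a turned to a log2 fold change of 0.027 with thinned counts and 0.023 with no doublets removed, and ranged from -0.25 to 0.15 with a library left out, etv4 from -0.39 to 1.25 and mt-cyb from -0.085 to 0.74. In osteoprogenitor-like and mesenchymal-like cells fap turned to 0.017 when clustered without genes that differ, saa to -0.064 with a mitochondrial share of up to 20%, and fgfr2 ranged from -0.039 to 0.41. In the clusters matching OP5 fgfr1b ranged from -1.37 to 0.20, fgfr2 from -0.34 to 0.052 and hbbe2 from -0.15 to 4.56. The cause was not tested.

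The difference in cycling share turned to -9.11 percentage points without thinning (-5.31 in osteoblast-like and -9.83 in osteoprogenitor-like and mesenchymal-like cells). Without thinning the cut on UMIs of the list depends on the UMIs per cell, which differed between libraries. This value therefore does not compare cycling, and how much of the turn depth explains was not tested. With a library left out it ranged from 0.0533 to 4.77, and in osteoblast-like cells from -0.319 to 2.01. In the authors' deposited tables, OB held 37 genes and OP5 84 with the same sign in at least 3 of 4. In all 4, 6 and 25 genes had the same sign with the authors' adjusted p under 0.05. Each of these comparisons sets 1 fish against 1 fish, so its p-values rest on cells and do not measure the spread between fish. The difference of effects gave 63 genes against osteoprogenitor-like and mesenchymal-like cells and 164 against the clusters matching OP5 with no filter on low counts, and 2 to 25 and 19 to 136 with a library left out.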

Other observations

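The test of immediate early genes, the limit on free RNA behind heat shock genes, and the gene tests in clusters 5 and 12 with the genes named there, were chosen only after the results were seen. Unnamed cluster 5, which shares markers with osteoprogenitor-like cells, had fgfr3 at 123, 150, 48.7 and 48.3 CPM before normalisation. The cartilage collagen gene col9a2 stood there at 133, 52.2, 11.2 and 7.40 CPM (-3.29, SE 0.50). By edgeR 0 of 8124 genes passed in this cluster, 316 had an unadjusted p under 0.05 and DESeq2 called 16. In unnamed cluster 12, led by tnfrsf9a and il2rb, 0 of 5258 passed by edgeR, 213 had an unadjusted p under 0.05 and DESeq2 called 2. In both clusters the genes at an unadjusted p under 0.05 were a smaller fraction than the 0.05 that no effect would give.

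Of 5080 genes tested in at least 8 of 11 classes and unnamed clusters, 28 were picked by a rule. They had the same direction wherever tested, and an unadjusted edgeR p under 0.05 in at least 0.5 of those classes. Their small p-values are thus part of the rule and not a result. Among them were selenok (11 of 11 classes at an unadjusted p under 0.05, median log2 fold change 2.04), a ribosomal protein gene copy named rpl26 (11 of 11, -1.69) and hsp70l (9 of 11, -2.06). Variants carried along with the fgfr3 allele could give such genes, but of 22 placed genes other than fgfr3 1 lay on its chromosome (4.55%), against 3.902% of the other tested genes (Fisher's exact test, p 0.584). This lookup placed 82.14% of the genes only after older symbols had been matched. Free RNA is argued against for 25 of the 28 genes; the other 3 had a median level in the classes under 0.5 times that in barcodes of 1 to 100 UMIs, bglap at 0.026 times, si:dkey-183i3.5 at 0.02 and zgc:136930 at 0.02, and for these it stays open. Variants elsewhere in the genome, differences between the 4 fish and an effect of the genotype in every class stay open and were not tested.

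Heat shock genes were lower in both fgfr3lof/lof than in both fgfr3+/+ libraries in 9 of 10 classes, at summed levels of 3180.6, 2607.2, 2043.7 and 1760.0 CPM in osteoblast-like cells and 1306.2, 1318.3, 448.9 and 337.1 in meningeal-like cells. A handling or dissociation difference between libraries could move them, and immediate early genes would then be lower too: their median was below -0.3 in 4 of 10 classes and above -0.1 in 3. Free RNA, with heat shock genes at 2095.5, 2077.3, 1091.2 and 628.2 CPM, is argued against: the fgfr3+/+ level of the classes lay above it in 3 of 10, a count between the bounds set, but its share of a class is limited by transcripts of other cells. From bglap (krt5 in osteoblast-like cells, upper 95% Poisson bounds), free RNA could bring at most 13.79% of the fall in any of the 9 classes, and 21.95% with a library left out (T cell-like cells without fgfr3+/+ 1). The count for immediate early genes lies between the bounds set, so it does not decide on handling. Their summed levels were 20223.1, 18628.2, 24060.7 and 14083.7 CPM in osteoblast-like cells, highest in fgfr3lof/lof 1. In meningeal-like cells they were 37142.4, 25883.5, 25820.3 and 18260.9, lower in both fgfr3lof/lof libraries. Each library was 1 fish, so a difference in its handling cannot be told apart from the genotype by these values.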
